A study of Homo sapiens with 8 samples.

How the data were processed

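Gene expression was measured in 1.1B4 cells, a human pancreatic islet-derived hybrid cell line, on 8 one-colour Agilent arrays of the 4x44K v2 design. The labels put 3 arrays in the control group, 3 in the NR4A3 siRNA group, 1 in the H2O2 group and 1 in the group given both. Per the labels' protocols, the control dishes received nuclease-free water in place of siRNA, so the comparison holds the transfected RNA itself as well as its target. The siRNA was applied for 48 h and cells were collected at 72 h, or at 74 h where H2O2, given by the labels as 100 mM, a unit not checked here, was added for 2 h. Each array holds RNA combined from 3 dishes, of 12 dishes per arm, and 100 ng of RNA was labelled with Cy3. No label says that the arrays of a group came from separate experiments, so p-values measure only the spread between these samples, which can be technical.

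Each scanner file gives spot intensity values made by Agilent Feature Extraction 9.5.1.1, per the file headers. The intensity used was the processed signal, which per the file headers was background-adjusted and detrended within the array, with surrogate values near background and no scaling between arrays. Other columns hold flags, per the file headers. Those for control type and outliers were used to filter spots, and that for well above background to filter probes. The flag for saturation was only counted. The authors also deposited a table of 24297 probes with an intensity column per array and ratio columns between group averages. Its per-array intensity values were found to be within 0.1% of the scanner values for 97.1% to 97.2% of probes, so they were not scaled between arrays, and the median of a column ran from 611.7 to 827.0. The ratio columns that the authors deposited are on a compressed scale. Their log2 rose by 0.437 to 0.440 for each unit of log2 ratio in the scanner values, with r of 0.997 to 0.998 across probes, so they were not read as folds. How the averages behind them were made is not given in the sources used here.

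For each array, log2 of the processed signal was taken at 43118 spots after 1377 control spots were left out, and the array's 75th percentile of it was subtracted. Outlier spots were left out, saturated ones were kept, and spots of 1 probe were averaged. Of 34127 probes, the 20491 well above background on at least 2 of the 8 arrays were kept. The kept probe of highest mean log2 signal stood for its gene, which left 16533 genes, with 27 gene and array values missing. Gene names came from the files' accessions through a RefSeq table of assembly GRCh38.p14, used for names only. It named 24826 probes by accession, 1188 by symbol and 472 by synonym, and 7641 kept the file's name. Probe coordinates are those of the files, on hg19. XIST and Y-linked genes are not reported.

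Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The siRNA effect compared 3 siRNA with 3 control arrays. The H2O2 effect came from an additive model of siRNA and H2O2 over all 8 arrays, which assumes an equal siRNA effect with and without H2O2. The H2O2 effects without and with siRNA, and their difference (the interaction), came from a model with 1 mean per group. There the single H2O2 arrays were assumed to vary like the other groups, since the spread comes from the 6 arrays without H2O2. Of 31 gene lists fixed before the data were examined, the 30 with at least 3 genes tested were tested with camera (preset inter-gene correlation 0.01, adjusted over lists). Beside it stand camera with an estimated correlation, whose adjusted p is printed as such, and counts of members past the threshold. For these counts the adjustment was over all genes, and again over the list alone. A probe not well above background on any array of a group has only a bound there. The text then gives "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The number of arrays limits the precision of every value.

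Scanner flags put 54.9% to 58.8% of probes well above background on an array, and the 75th percentile of the signal ran from 2271 to 2959. Between 1 and 4 probes were saturated per array. Slide 1 held controls 1 and 2 and siRNA arrays 1 and 2, and slide 2 held the other 4. Scans followed the slides. The siRNA arrays lay at positions 2 and 4 and both H2O2 arrays at positions 3 and 4 of slide 2, so slide was used as a block and values are given within slides.

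Named genes followed a rule set before the data were examined. It took NR4A3, NR4A1, NR4A2 and INS. It then took the 10 rises and 10 falls of largest log2 difference past the threshold that had an official symbol. For siRNA these also had separated groups and a brighter group well above background on every array. For H2O2 they had the same sign with and without siRNA, and were well above background on both H2O2 arrays for a rise or on all 6 others for a fall. Up to 4 members of each list past the threshold were added, or the 2 of smallest p where camera called a list with no such member. For the interaction, the 3 largest values in each direction past the threshold were taken among genes with an official symbol. This gave 138 genes for siRNA and 80 for H2O2.

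The tests were run on simulated data of 16510 genes, 200 of them changed. The noise was normal and independent between genes, with each gene's spread taken from the arrays without H2O2. It held no slide or position effect, no correlation between genes and no local marks on an array. Far fewer genes were changed than the 9438 of 16533 that the siRNA comparison called, and the changes were added after scaling between arrays. The recovered shares and false calls below therefore do not cover these conditions. For the siRNA comparison, 68.7% of genes changed 1.5-fold, 85.1% of those changed 2-fold and 87.9% of those changed 4-fold were recovered, with 9 false calls. For the additive H2O2 model these shares were 76.1%, 91.0% and 84.8%, with 7 false calls. For the interaction they were 31.3%, 64.2% and 75.8%, with 6 false calls. A list shifted by 0.5 on the log2 scale was called in both comparisons, along with 1 unshifted list of the 30 in each. Alternatives tried were normexp background correction (offset 50), quantile normalization, the deposited values (scaled here by their own 75th percentile, since they were unscaled), other filters on dim probes, the mean of all probes of a gene, replicate and slide blocks, an additive siRNA model, trended robust eBayes, a 2-fold minimum and leaving out each array. Figures were drawn with matplotlib 3.10.9.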

Results

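The series measured how an siRNA against NR4A3, an orphan nuclear receptor of the NR4A family, and the oxidant H2O2 changed gene expression in 1.1B4 cells. It holds 8 arrays, with 3 of control cells, 3 of cells given NR4A3 siRNA, 1 of cells given H2O2 and 1 of cells given both. Values are log2 signals relative to the 75th percentile of the array, and differences between groups are on the log2 scale, with the standard error (SE) of the fit. Arrays of 1 group correlated at r = 0.989 to 0.991 across genes and arrays of the siRNA and control groups at 0.977 to 0.980, where genes are not independent replicates.

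The targeted gene was examined first. Neither NR4A3 probe was well above background on any of the 8 arrays, so the knockdown could not be assessed at the RNA level. The probe A_23_P306867 (chromosome 9, 102595751 to 102595810, hg19) read -6.90 ± 0.12 (SD, n = 3) in controls and -7.15 ± 0.16 (SD, n = 3) with siRNA, a difference of -0.25 (exact permutation test, two-sided p = 0.2). The probe A_23_P398566 (chromosome 9, 102628985 to 102629044) read -6.80 ± 0.13 and -7.00 ± 0.15, a difference of -0.20 (exact permutation p = 0.3). The smallest p that 3 arrays against 3 allow is 0.1. The NR4A1 probe and an NR4A2 probe were likewise not well above background on any array, and the other NR4A2 probe was so on 3 arrays, with a difference of 0.15 ± 0.16 (SE, adjusted p = 0.467). INS, which encodes insulin, was bright on all 8 arrays (chromosome 11, 2181064 to 2181123). It rose from 2.04 ± 0.07 (SD, n = 3) to 2.64 ± 0.004 (SD, n = 3), or 1.51-fold (limma adjusted p = 2.37e-04). The difference was 0.64 within slide 1, 0.51 within slide 2 and 0.49 between the H2O2 arrays.

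**Figure D1:**
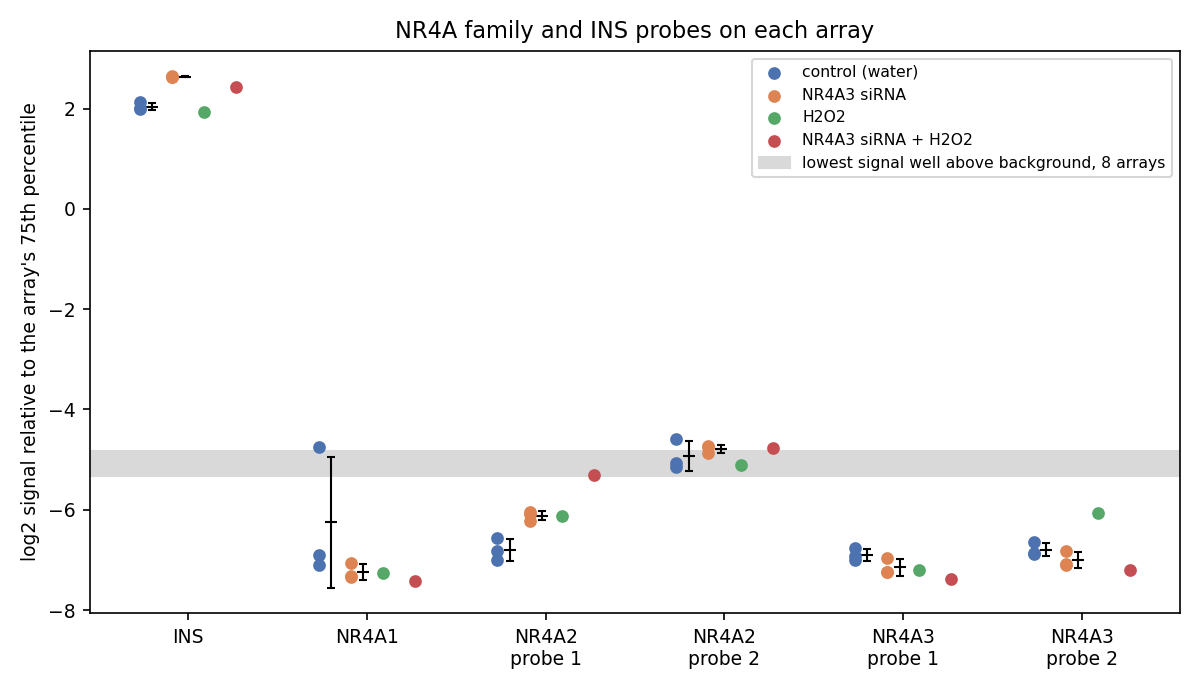
Log2 signal of the INS and NR4A family probes relative to the 75th percentile of each array, with a point per array, coloured by group, and black bars for the mean and SD of the groups of 3. The NR4A3 probes lie below the grey band of the lowest signals well above background on the 8 arrays, and the INS points with siRNA lie above those without.

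With NR4A3 siRNA, the largest rises that were measured in both groups were those of BMF, CES1, RNF43 and SLITRK6. BMF, a pro-apoptotic member of the BCL2 family (chromosome 15, 40380450 to 40380509), rose by 3.70 ± 0.07 (SE), or 13.0-fold (limma adjusted p = 1.93e-05). CES1, a carboxylesterase, rose by 3.06 ± 0.04 (SE), RNF43, a ubiquitin ligase that restrains Wnt signalling, by 2.76 ± 0.13 and SLITRK6, a transmembrane protein, by 2.62 ± 0.14. The other genes among the largest rises were not well above background in controls. They rose at least 3.86-fold for HGC6.3, at least 3.62-fold for GPNMB, at least 2.38-fold for PPP1R1B, at least 2.05-fold for KIF5A, at least 1.85-fold for SCGB1D2 and at least 1.81-fold for RAB17. Among genes measured in both groups, TMEM158 fell by 2.37 ± 0.04 (SE), THBD, which encodes the anticoagulant receptor thrombomodulin, by 2.19 ± 0.07, HNRNPAB, an RNA-binding protein, fell by 2.15 ± 0.06 and KRTAP19-5 by 2.09 ± 0.06. The genes that fell to below background were OR6C65, at least 4.36-fold lower, SPOCD1, at least 2.73-fold, DGKG, at least 2.18-fold, IGFBP1, at least 1.99-fold, and MYL11, at least 1.81-fold lower. SBSN was at least 2.06-fold lower (adjusted p = 0.0346), but its call was lost in 7 of 15 alternative runs, with adjusted p up to 0.0961, among them the slide and replicate blocks and the runs without controls 1 and 3 or siRNA arrays 1 and 3. By the rule that named them, the groups did not overlap for any of these genes, which chance gives for 10% of genes. BMF differed by 3.60 within slide 1 and 3.90 within slide 2, CES1 by 3.04 and 3.10 and TMEM158 by -2.34 and -2.44.

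In all, 9438 of 16533 genes (57.1%) passed the threshold with siRNA, 4661 of them higher and 4777 lower. Most differences were small, with a median size of 0.38 among the called genes, and 758 were at least 2-fold, 509 higher and 249 lower. Without scaling between arrays, 7528 genes passed, 6261 higher (83.2%) and 1267 lower, against 49.4% higher with it. The median of all genes was then 0.20 higher with siRNA, against -0.02 with scaling, so directions are given relative to the 75th percentile of the array. With slide as a block, 9110 genes passed, as did 134 of the 137 called genes named for siRNA, and all 137 kept their sign.

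Relative to the 75th percentile, ribosomal protein and mitotic genes were lower with siRNA and cell cycle inhibitors higher. Of 30 tested, 26 fell and 0 rose (1 rose and 27 fell when adjusted over the list alone), with a median of -0.29, and RPS6 fell by 0.52 ± 0.03 (SE). Camera gave adjusted p = 2.42e-06 with the preset correlation, while the adjusted p = 0.359 with an estimated correlation, and the call was lost with quantile normalization (adjusted p = 0.490). The count depended on the scaling, with 9 ribosomal protein genes lower and 3 higher under quantile normalization and 4 lower and 1 higher without scaling. Of mitotic genes, 22 of 30 fell against 1 that rose (23 and 1 adjusted over the list alone), with a median of -0.32, and without scaling 7 were lower and 3 higher. TOP2A, the mitotic topoisomerase, fell by 0.98 ± 0.04 (SE), UBE2C by 0.95 ± 0.04 and CDC20, an activator of the anaphase-promoting complex, by 0.82 ± 0.05 (camera adjusted p = 9.03e-05, and adjusted p = 0.359 with an estimated correlation). Of 9 cell cycle inhibitors, 7 rose and 0 fell, over all genes as well as adjusted over the list alone, among them CDKN2D by 0.84 ± 0.06 and CDKN1B by 0.77 ± 0.05 (camera adjusted p = 0.0237, with adjusted p = 0.359 with an estimated correlation and 0.0587 without scaling). Within slides 1 and 2 the ribosomal medians were -0.29 and -0.28, the mitotic ones -0.28 and -0.32 and those of the inhibitors 0.30 and 0.38. Of the DNA replication list, 8 of 32 were higher and 8 lower (camera adjusted p = 0.929), against 16 and 2 without scaling and 15 and 7 with quantile normalization. CCNE1 fell by 1.14 ± 0.05, while CDC6 rose by 0.50 ± 0.06.

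Genes of beta cell hormones and secretion rose, 11 of 16 tested against 1 that fell (12 and 1 adjusted over the list alone), with a median of 0.58. The prohormone-derived secretory peptide gene VGF rose by 0.79 ± 0.04 (SE) and PTPRN2, of the granule membrane, by 0.82 ± 0.10. SCG2, a granin, and SLC30A8, the zinc transporter of insulin granules, rose from below background, at least 2.09-fold and at least 1.51-fold. Camera gave adjusted p = 0.0237, with adjusted p = 0.359 with an estimated correlation, and without the filter on dim probes the call was lost (adjusted p = 0.183). The median was 0.52 within slide 1 and 0.55 within slide 2. Of 14 islet transcription factors, 5 rose and 2 fell (camera adjusted p = 0.314), with ISL1 up by 1.13 ± 0.10, INSM1 up by 0.82 ± 0.10 and PAX6 at least 1.74-fold higher, while GATA6, above background on all controls and 1 siRNA array, had a difference of -0.63 ± 0.10. Of the other islet hormone list, 2 of 7 tested rose, 1 when adjusted over the list alone (camera adjusted p = 0.358), and of 7 acinar genes 2 rose and 2 fell (0.991). Of 17 ductal and epithelial markers, 8 fell and 1 rose (0.0970), against 3 lower and 5 higher without scaling. CLDN1, a tight junction protein, fell by 1.38 ± 0.05. Of 11 leukocyte genes, 2 rose, CD14 by 1.64 ± 0.06, and 3 fell (0.978). Adjusted over the list alone, the counts of the transcription factor, acinar, ductal and leukocyte lists were equal to these.

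Interferon and double-stranded RNA response genes rose in 16 of 30 cases and fell in 6 (17 and 6 adjusted over the list alone), with a median of 0.33. OASL rose by 1.44 ± 0.13 (SE), IFITM1 by 1.30 ± 0.05 and IRF9, a subunit of the interferon-activated factor ISGF3, by 1.15 ± 0.06. Camera gave adjusted p = 0.0237, and adjusted p = 0.359 with an estimated correlation. Cholesterol synthesis genes rose in 11 of 22 cases and fell in 3 (13 and 3 adjusted over the list alone), with TM7SF2 up by 1.10 ± 0.06 and MSMO1 by 0.69 ± 0.07 (camera adjusted p = 0.0237, and adjusted p = 0.642 with an estimated correlation). The interferon medians were 0.41 and 0.28 within slides 1 and 2 and the cholesterol ones 0.25 and 0.15. Heat shock genes fell in 16 of 23 cases and rose in 3, over all genes and adjusted over the list alone. SERPINH1, a collagen chaperone, fell by 1.09 ± 0.04 and FKBP4, a cochaperone of HSP90, by 0.80 ± 0.05, while HSPB8 rose by 0.81 ± 0.06. Camera gave adjusted p = 0.0237, with adjusted p = 0.449 with an estimated correlation and 0.0869 with quantile normalization. Genes of the unfolded protein response and ATF4 fell in 15 of 28 cases and rose in 3, also when adjusted over the list alone. SDF2L1 fell by 0.63 ± 0.04 and ASNS, asparagine synthetase, by 0.53 ± 0.03. Here camera gave adjusted p = 0.0261, with adjusted p = 0.359 with an estimated correlation, 0.191 with quantile normalization, 0.0696 with no filter on dim probes and 0.0587 without scaling. The heat shock medians were -0.30 and -0.26 within slides 1 and 2 and the unfolded protein response ones -0.22 and -0.19. Without scaling 5 heat shock genes were lower and 6 higher, and the unfolded protein response median turned to 0.05, with 3 lower and 6 higher. All 8 lists called by camera for siRNA were called with slide as a block as well.

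In the remaining lists members went both ways or the list test did not pass. Of 22 NF-kB and inflammatory genes, 14 fell, CD83 by 1.35 ± 0.03 (SE) and IL11 by 1.26 ± 0.08, while 4 rose, CXCL1 by 1.14 ± 0.13 (camera adjusted p = 0.0562). Of 32 immediate early genes 16 fell and 2 rose (0.0562), and of 22 short-lived transcripts 10 fell and 2 rose (0.262). Glycolytic genes fell in 14 of 21 cases and rose in 5 (0.0645), HK1 falling by 0.84 ± 0.04 and ENO2 rising by 1.36 ± 0.04. Of 28 NRF2 and antioxidant genes, 12 fell, HMOX1, the heme-degrading oxygenase, by 1.004 ± 0.09, and 7 rose (0.609). Apoptosis regulators rose in 10 of 26 cases and fell in 9 (0.879), with HRK up by 1.14 ± 0.03. For 25 p53 targets, 9 rose, BBC3 by 0.75 ± 0.05, and 12 fell, GADD45A by 0.77 ± 0.03 (0.929), and the median of -0.10 and the mean of 0.04 differed in sign. They also differed in sign for the DNA replication list, at 0.04 and -0.03. Of 18 hypoxia genes 7 rose and 5 fell (0.879), with NDRG1 up by 1.17 ± 0.05 and ADM down by 1.01 ± 0.03. Matrix and mesenchymal genes fell in 10 of 20 cases and rose in 4 (0.314), where COL1A1 fell by 1.001 ± 0.05 and SNAI2, a repressor of epithelial genes, fell to below background, at least 3.20-fold lower. Oxidative phosphorylation genes fell in 11 of 29 cases and rose in 2 (0.0772), autophagy and lysosome genes rose in 10 of 26 and fell in 5 (0.314), and fatty acid genes rose in 10 of 20 and fell in 6 (0.575). DNA repair genes fell in 8 of 30 cases and rose in 4 (0.314), histones fell in 4 of 14 and rose in 1 (0.879), metallothionein and metal response genes fell in 4 of 10 and rose in 3 (0.879), and RNA silencing factors rose in 4 of 13 and fell in 4 (0.929). Adjusted over the list alone, 10 p53 targets were higher and 13 lower and 9 short-lived transcripts were lower, with equal counts for the other lists here. Median and mean also differed in sign for the metal response, acinar, leukocyte and RNA silencing lists. Without scaling, the genes higher and lower were 5 and 5 for the NF-kB list, 5 and 4 for the glycolytic, 9 and 8 for the immediate early, 10 and 3 for the antioxidant, 11 and 3 for the p53, 4 and 4 for the matrix and 5 and 0 for the oxidative phosphorylation list. They were 5 and 2 for the short-lived, 6 and 3 for the DNA repair, 7 and 0 for the histone, 3 and 0 for the metal response, 5 and 1 for the RNA silencing, 13 and 5 for the apoptosis, 9 and 2 for the hypoxia, 13 and 0 for the autophagy and 11 and 1 for the fatty acid list. For immediate early genes camera then called the list lower (adjusted p = 0.0262) although the median was 0.03, and with scaling it had adjusted p = 0.660 with an estimated correlation. Quantile normalization turned the oxidative phosphorylation, antioxidant and metal response counts to 8 and 6, 8 and 7 and 4 and 0. Medians of 13 lists turned sign without scaling, among them the immediate early, short-lived, DNA repair, histone, oxidative phosphorylation, p53, antioxidant, ductal and matrix lists, and those of 7 lists with quantile normalization.

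**Figure D2:**
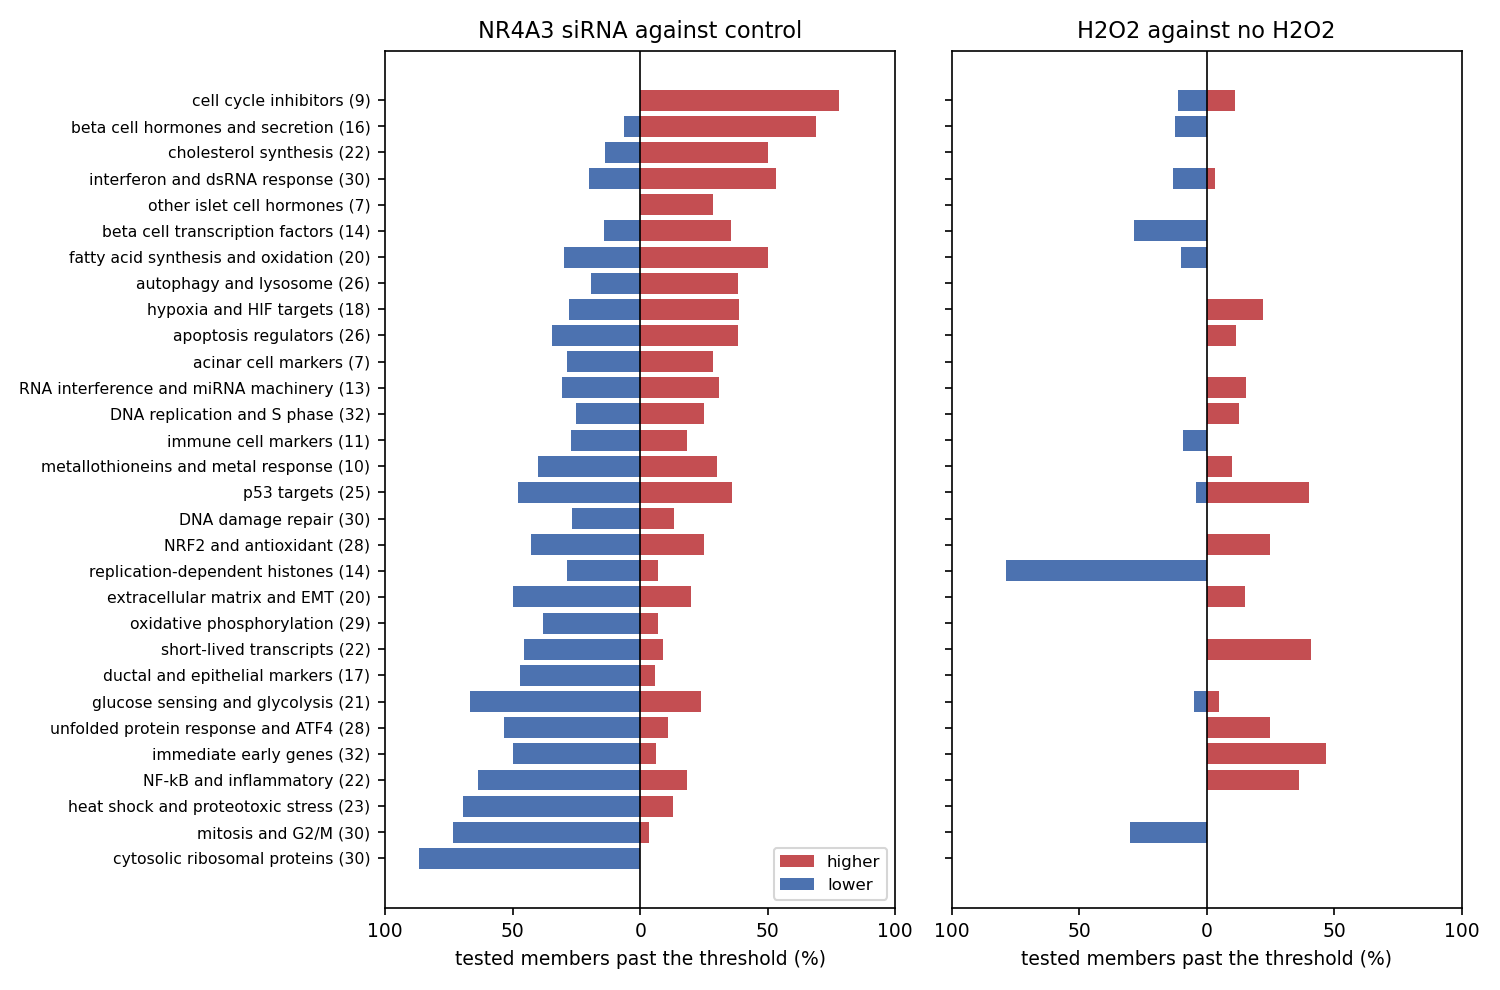
Percent of the tested members of each fixed gene list that were higher (red) or lower (blue) past the threshold, with the number tested in brackets, for NR4A3 siRNA against control on the left and H2O2 against no H2O2 on the right. With siRNA 26 of 30 ribosomal protein genes were lower relative to the 75th percentile of the array, and with H2O2 15 of 32 immediate early genes were higher and 11 of 14 histone genes lower.

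The 2 arrays with H2O2 gave a separate estimate of the siRNA effect, with no array in both. Of the 9438 genes called without H2O2, 9045 (95.8%) had the same sign between the H2O2 arrays with and without siRNA, and of the 758 changed at least 2-fold, 740 did. Over all genes r was 0.651 across genes, which are not independent replicates. BMF differed by 3.69, CES1 by 2.79 and TMEM158 by -2.204 under H2O2. OR6C65 and MYL11, not well above background on either H2O2 array, differed by -0.15 each there, and IGFBP1, above background on both, by 0.01. With 1 array per group this comparison has no replicate check.

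With H2O2, ATF3, OSGIN1 and GADD45A rose and 11 of 14 replication-dependent histone genes fell in the additive model (camera adjusted p = 1.07e-10 for the list). The dose that the labels give, 100 mM, is high for cultured cells and its unit was not checked here, so no effect is tied to a dose. ATF3, a stress-induced transcription factor (chromosome 1, 212793856 to 212793915), rose by 1.40 ± 0.07 (SE), or 2.63-fold (limma adjusted p = 0.001002), by 1.26 without and 1.53 with siRNA. OSGIN1, an oxidative stress-induced gene, rose by 1.38 ± 0.05, HMOX1 by 1.04 ± 0.13 and GADD45A by 0.88 ± 0.03. Above background on both H2O2 arrays and 3 of the other 6 were FOSB, with a difference of 1.54 ± 0.32, and CXCL8, the chemokine interleukin-8, with 1.37 ± 0.14. Measured only with H2O2 were FHL5, at least 2.80-fold higher, CSF2RB, at least 2.62-fold, RNU4ATAC, at least 2.38-fold, LIN28A, at least 2.34-fold, the immediate early gene EGR4, at least 1.75-fold, and PPP4R1L, at least 1.04-fold. ISL1 fell by 1.53 ± 0.16 and the linker histone genes H1-3 by 1.08 ± 0.06 and H1-5 by 0.91 ± 0.03. TAGLN3, above background on 1 H2O2 array and all 6 others, had a difference of -0.99 ± 0.16. H2AC4, RNF43, H3C2, H2BC7 and SIRT4 fell by 0.79 to 0.92, and ACP4 was at least 2.21-fold lower.

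In this model 930 of 16533 genes passed the threshold, 513 higher and 417 lower, 21 of them by at least 2-fold. Slide 2 held both H2O2 arrays, and with slide as a block 196 genes passed, 120 higher and 76 lower. Without scaling between arrays 74 genes passed, 67 higher and 7 lower. Of the 76 called genes named for H2O2, 34 stayed past the threshold with the slide block and all 76 kept their sign. ATF3 then differed by 1.35 (adjusted p = 0.0101), OSGIN1 by 1.34 (0.00309) and H1-3 by -1.03 (0.0101), while HMOX1, at 1.05, had an adjusted p of 0.0669 and ISL1, at -1.46, of 0.0517. The call was also lost with the slide block for FHL5, CSF2RB, LIN28A, PPP4R1L, FOSB, TAGLN3, RNF43 and SIRT4, and for the list members TRAF1, DDIT3, CDKN1A, ACSL3, SREBF1 and SNAP25 named below. With no filter on dim probes another probe stands for CSF2RB, and its difference turned to -0.19. Over all alternative runs, LIN28A lost it in 13 of 16 (adjusted p up to 0.597), FHL5 in 11 of 16 (0.291), PPP4R1L in 11 of 16 (0.620), FOSB in 12 of 17 (0.517), TAGLN3 in 10 of 17 (0.475) and RNF43 in 9 of 18 (0.550). Each of these 6 lost it without siRNA array 3 and without either H2O2 array. Without siRNA array 1 the call was lost for all of them but PPP4R1L, without siRNA array 2 for LIN28A and FHL5, without control 1 for LIN28A, PPP4R1L and FOSB, without control 2 for PPP4R1L, FOSB and TAGLN3, and without control 3 for LIN28A, FHL5, PPP4R1L and FOSB. Without the array given both treatments the call was also lost for HMOX1, SIRT4, H2BC7, DDIT3, CCNE2, SREBF1, TRAF1, SNAP25 and CDKN1A, and without that given H2O2 alone for ACSL3, TRAF1 and CDKN1A. SNAP25 lost it in 8 of 18 runs (up to 0.554), among them without siRNA arrays 2 and 3, and CDKN1A in 14 of 18 (0.597), among them without controls 2 and 3 and any 1 siRNA array. Within slide 2, ATF3 differed by 1.18 without and 1.52 with siRNA.

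Immediate early genes rose as a group with H2O2, 15 of 32 with 0 falling (21 and 0 adjusted over the list alone), with a median of 0.34, and MAFF rose by 0.99 ± 0.07 (SE). Camera gave adjusted p = 4.01e-15, and adjusted p = 0.0740 with an estimated correlation. Of 14 replication-dependent histone genes 11 fell and 0 rose, over all genes and adjusted over the list alone, with a median of -0.39, and H3C4 fell by 0.74 ± 0.05. Mitotic genes fell in 9 of 30 cases (21 adjusted over the list alone), TOP2A by 0.47 ± 0.04, and 8 of 22 NF-kB and inflammatory genes rose (11 adjusted over the list alone), TRAF1 by 0.55 ± 0.08. These 3 lists were called with the preset correlation (camera adjusted p = 1.07e-10, 3.28e-12 and 4.40e-08) and held with an estimated one (adjusted p = 0.0294 each). Within slide 2, the immediate early median was 0.28 without and 0.50 with siRNA, and the histone median -0.39 and -0.37. With slide as a block 9 immediate early genes and 1 NF-kB gene were higher and 6 histone genes and 1 mitotic gene lower, while the medians were 0.40, 0.19, -0.39 and -0.17 and camera called all 15 lists called without it. Without scaling 9 immediate early genes and 1 NF-kB gene were higher and 0 histone and 0 mitotic genes lower, with medians of 0.44, 0.29, -0.30 and -0.06, and camera called these 4 lists.

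The antioxidant, p53, unfolded protein response, short-lived, replication, apoptosis and hypoxia lists were higher by camera too, each losing the call with an estimated correlation. Short-lived transcripts rose in 9 of 22 cases (12 higher and 2 lower adjusted over the list alone), MYC by 0.51 ± 0.05 (SE), with adjusted p = 0.0800 with an estimated correlation. NRF2 and antioxidant genes rose in 7 of 28, also when adjusted over the list alone, among them SLC7A11, the cystine transporter, by 0.66 ± 0.06 and SRXN1 by 0.62 ± 0.04 (adjusted p = 0.277 with an estimated correlation). Unfolded protein response and ATF4 genes rose in 7 of 28 (8 adjusted over the list alone), CEBPB by 0.67 ± 0.03 and DDIT3, which encodes CHOP, by 0.65 ± 0.08 (adjusted p = 0.0828 with an estimated correlation). Of 25 p53 targets 10 rose and 1 fell (10 and 2 adjusted over the list alone), with PLK2 up by 0.57 ± 0.03 and CDKN1A, the p21 cell cycle inhibitor, by 0.64 ± 0.14 (adjusted p = 0.113 with an estimated correlation). Replication and S phase genes rose in 4 of 32 (6 higher and 1 lower adjusted over the list alone), CCNE2 by 0.40 ± 0.04 (adjusted p = 0.299 with an estimated correlation). Apoptosis regulators rose in 3 of 26 (6 adjusted over the list alone), BMF by 0.72 ± 0.07 (adjusted p = 0.0828 with an estimated correlation), and hypoxia genes in 4 of 18, also adjusted over the list alone, ANGPTL4 by 0.69 ± 0.05 (adjusted p = 0.230 with an estimated correlation). The last pair lost the call also without the array given H2O2 alone (adjusted p = 0.0684 and 0.138). Without scaling 5 antioxidant, 5 p53, 4 unfolded protein response, 1 short-lived, 0 replication, 1 apoptosis and 1 hypoxia gene were higher. With slide as a block 3 antioxidant, 4 p53, 2 unfolded protein response, 3 short-lived, 2 replication, 2 apoptosis and 2 hypoxia genes were higher. The medians were then 0.28 for short-lived transcripts, 0.02 for antioxidant genes, 0.01 for p53 targets, 0.03 for replication genes and 0.04 for apoptosis regulators. Those of the unfolded protein response and hypoxia lists turned to -0.0007 and -0.006.

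Lower by camera were fatty acid genes, 2 of 20 falling (4 lower and 1 higher adjusted over the list alone), ACSL3 by 0.39 ± 0.05 (SE) and SREBF1, the lipogenic factor SREBP1, by 0.37 ± 0.05 (adjusted p = 0.0740 with an estimated correlation), and beta cell hormone and secretion genes, 2 of 16 falling (7 lower and 1 higher adjusted over the list alone), SNAP25 by 0.36 ± 0.06 (adjusted p = 0.348 with an estimated correlation). Ribosomal protein and oxidative phosphorylation genes were called with 0 members past the threshold (adjusted p = 0.569 with an estimated correlation for each), over all genes and adjusted over the list alone, and quantile normalization ended both calls. Of 19 alternative runs, the hormone call held in 9, the ribosomal in 7 and the oxidative phosphorylation call in 6. With a position block their adjusted p were 0.0824, 0.149 and 0.592. Without the array given both treatments the hormone list had adjusted p = 0.348 and the oxidative phosphorylation list 0.626, and without that given H2O2 alone the ribosomal list had 0.438. With slide as a block the fatty acid, hormone, ribosomal and oxidative phosphorylation medians were -0.11, -0.18, -0.07 and -0.07. Of 14 islet transcription factors 4 fell (5 lower and 2 higher adjusted over the list alone, camera adjusted p = 0.0583). With slide as a block 1 fell and camera gave adjusted p = 0.0225. With an estimated correlation, run without blocks, it gave adjusted p = 0.211. Of 30 interferon genes 4 fell and 1 rose (5 and 1 adjusted over the list alone, camera adjusted p = 0.111). Glycolytic genes had 1 higher, PFKFB3 by 0.80 ± 0.04, and 1 lower (camera adjusted p = 0.917), and cell cycle inhibitors 1 of each (0.388). Matrix genes had 3 higher (0.402), RNA silencing factors 2 (0.917), metal response genes 1 (0.608), and the leukocyte list 1 lower (0.642). No member passed in the heat shock, cholesterol, autophagy, DNA repair, ductal, other islet hormone and acinar lists, whose camera adjusted p ran from 0.102 for cholesterol to 0.876 for other islet hormones. The slide block made camera call the cholesterol list lower as well (adjusted p = 0.00845, median -0.11). With an estimated correlation, run without blocks, camera gave this list adjusted p = 0.633. Adjusted over the list alone, 2 autophagy genes were higher, and 1 more gene was lower in each of the inhibitor, matrix and RNA silencing lists. Median and mean differed in sign for the metal response, autophagy, DNA repair, matrix and ductal lists. Without scaling, 0 hormone, fatty acid, interferon and leukocyte genes and 1 islet transcription factor passed. Medians of 14 lists turned sign without scaling between arrays, among them the fatty acid, ribosomal and oxidative phosphorylation lists.

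**Figure D3:**
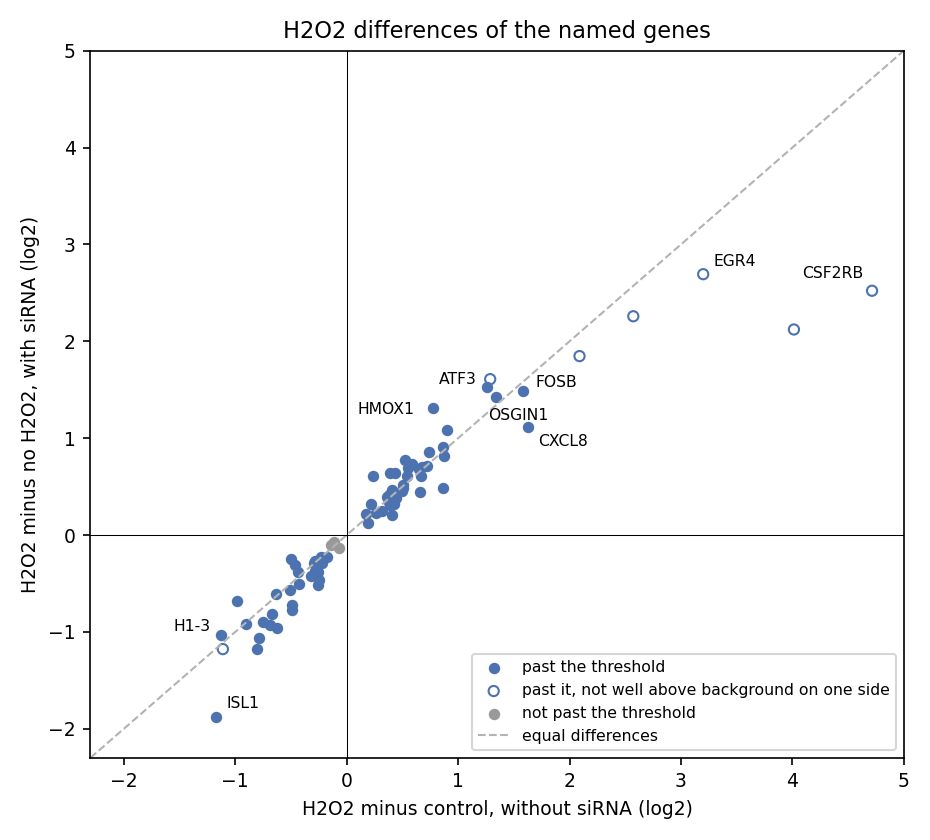
Log2 difference with H2O2 for each gene named in the H2O2 comparison, without siRNA on the horizontal and with siRNA on the vertical axis, each from 1 H2O2 array. The largest rises and falls were chosen to have the same sign in both, so their place near the line of equal differences is partly set by that choice. ATF3 lies at 1.26 and 1.53 and ISL1 at -1.17 and -1.88.

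Taken separately, each H2O2 effect rests on 1 array with no replicate, which was assumed to vary like the arrays without H2O2. On that assumption 271 genes passed the threshold without siRNA (161 higher, 110 lower) and 354 with it (187 higher, 167 lower). With slide as a block these counts were 29 and 10. The calls shared 132 genes in the same direction, against 2.93 for independent lists. The H2O2 arrays and their references differ between the estimates, but both take the spread of each gene from the same 6 arrays, which by itself makes calls coincide. Of the 271 genes, 241 had the same sign with siRNA, and of the 354, 331 had it without. Over all genes the differences correlated at r = 0.141 across genes. The test of the difference between both H2O2 effects called 18 genes, 9 in each direction, with 1480 at an unadjusted p under 0.05, and 1 gene with slide as a block.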

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

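The tests of array marks and of slide and position given here were chosen after the results were seen. The H2O2 effect differed with siRNA past the threshold for 18 genes, each resting on 1 array per H2O2 group. Those without an official symbol reached -2.34 (ENST00000324928). Among genes with one, the largest positive differences were 4.92 for RAD9A, 4.23 for OR6C65 and 2.79 for RNPS1. The largest negative ones there were -1.39 for MED12, -1.25 for DHODH and -1.11 for ENTPD6. RNPS1 kept the call in all 14 alternative runs. The other 5 lost it with slide as a block, and over all runs RAD9A in 6 of 14 (adjusted p up to 0.124), OR6C65 in 8 of 12 (0.156), MED12 in 8 of 14 (0.238), DHODH in 5 of 14 and ENTPD6 in 7 of 14 (0.0960 each). All 5 lost it without control 2 or 3 or siRNA array 1 or 3, OR6C65, MED12 and ENTPD6 also without control 1, and RAD9A, OR6C65 and MED12 also without siRNA array 2. For OR6C65 the value reflects a probe not well above background on any array but the 3 controls.

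A local mark and a changed response were set against each other for these calls. If a local mark on an array were the cause, spots around the gene's own would shift the same way on that array. They did so for 8 of the 17 genes with readable neighbours, where 1% of random genes go as far. The 8 are CACNG6, COG7, DHODH, ENST00000402430, MED12, RAD9A, RNPS1 and USP27X. Because some lie side by side they make up 4 of 13 places on the arrays (exact binomial p = 6.65e-06 against 1%), and a local mark may account for them. Called genes at 1 place count among each other's neighbours, and a place counts if any of its genes does. The 1% holds for single random genes, so this p can be too small. DHODH was the only called gene at its place, and its neighbours shifted by 0.36, against a cut of 0.15. For the other 9, among them OR6C65 and ENTPD6, neighbours did not shift that far, and a change of the H2O2 response by siRNA, an uneven single spot and the lone array cannot be told apart without further arrays.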

How the results depend on the processing

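The runs without scaling between arrays and with position blocks were chosen after seeing the data. The siRNA count stayed within 1.5 times its value in every run except the 2-fold minimum (758 genes), and ran from 8083 to 8938 without 1 array. The main siRNA test did not pair arrays by replicate number. Each control and siRNA array correlated best with the other group's array of its own number, a hint of pairing from the data only. The correlations of deviations were 0.072, 0.063 and 0.141. Control and siRNA arrays of equal number also lay at adjacent positions of the same slide, so number and place cannot be told apart. With the replicate block 8454 genes passed. The siRNA list count of 8 became 5 with quantile normalization and 0 with an estimated correlation, and the H2O2 list count of 15 became 3 with an estimated correlation. The cause of the changes below was not tested, except that by construction blocks leave fewer residual degrees of freedom, left-out arrays fewer arrays and stricter thresholds fewer genes.

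For H2O2 over both siRNA states, without siRNA and with siRNA (930, 271 and 354 genes), normexp gave 565, 97 and 161, the slide block 196, 29 and 10, a 2-fold minimum 21, 48 and 37, and no scaling 74, 102 and 27. No scaling put 90.5% of the first and 91.2% of the second higher, against 55.2% and 59.4%, and quantile normalization put 70.1% of the second higher. No filter on dim probes gave 393 and 150 for the first 2. Probes well above background on all 8 arrays gave 412 and 608, and trended robust fits 512 and 676, for the last 2. The first count was 214 with a position block and 3 with slide and position blocks, where 0 of 76 called named entries passed and all 76 kept their sign. HMOX1 then differed by 1.11 ± 0.27 (SE), against 1.04 ± 0.13, and ISL1 by -1.49 ± 0.33, against -1.53 ± 0.16, and 14 of the 15 called lists held, without oxidative phosphorylation (adjusted p = 0.678). Without 1 array the counts ran from 271 to 718, from 46 to 117 and from 17 to 242, each left-out array lowering them by over 1.5 times except control 1 for the first (718) and last (242). The first was 271 without the array given both treatments, 354 without that given H2O2 alone, 448, 559 and 475 without siRNA arrays 1, 2 and 3, and 586 and 606 without controls 2 and 3. The interaction count of 18 was 11 with normexp, 144 with no filter, 1 with the slide block and 1 to 13 without 1 array, the highest without siRNA array 2.

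The same-sign share of siRNA effects under H2O2 (95.8%) was 95.3% with normexp, 97.2% with no filter, 95.4% with probes above background on all 8 arrays, 89.4% with no scaling and 93.9% to 97.3% without 1 array. The correlation of H2O2 effects (0.141) was 0.212 with normexp, 0.286 with the deposited values, 0.115 with no filter, 0.378 with probes above background on all 8 arrays, 0.0891 with the slide block and 0.106 to 0.156 without 1 array. The NR4A3 difference (-0.20) was -0.37 with normexp, -0.0024 with quantile normalization, -0.43 in the additive model and 0.028 with no scaling, all below background. It ran from -0.29 to -0.13 without 1 array. The additive model includes the H2O2 arrays, where this probe, A_23_P398566, read -6.07 without and -7.20 with siRNA. The other NR4A3 probe read -7.20 and -7.38 there, and neither probe was well above background.

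CYCS turned to 0.13 and LEPR to -1.05 with the mean of all kept probes, and CSF2RB under H2O2 to -0.19 with no filter, where another probe stands for the gene. The files place the probes of CYCS and FTH1 on chromosome 2, of LEPR and RPS3 on 6, of UHRF1 on 12, of RPS13 on 15 and of UQCRFS1 on 22, none of them the chromosome of the gene. Of the other runs of named genes, 2259 for siRNA kept direction and side, 51 lost the threshold and 1 gained it. For H2O2, 971 kept the side of the threshold and 450 lost it, and for the interaction 48 and 34 did. Among the 971, a gene never called could change direction, as RPS18 did, running from -0.17 to 0.0025. Kept probes of 235 of 3307 genes with several had opposite siRNA calls. Signal over background limits the values of the NR4A genes and of all genes given as bounds.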

Other observations

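The tests of slide, position, interferon genes and collection time given here were chosen after the results were seen, while the count over other splits of the arrays was planned. The cells showed part of a beta cell profile. INS was well above background on all 8 arrays, as was IAPP, which encodes islet amyloid polypeptide. No array had PDX1, NKX6-1, NEUROD1, NKX2-2, PCSK1, CHGA, KCNJ11 or SLC2A2 well above background, and 13 of the 30 beta cell hormone and secretion genes and 10 of the 25 islet transcription factors on the array were not well above background on any array. Keratin genes of simple epithelia, KRT8, KRT18, KRT19 and KRT7, were well above background on all 8 arrays. Whether the INS probe also reads the overlapping INS-IGF2 readthrough transcript was not checked.

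Genes that fell with siRNA included several that rose with H2O2. These pairs were chosen after their values were seen. HMOX1 differed by -1.004 with siRNA and 1.04 with H2O2 and GADD45A differed by -0.77 and 0.88. ISL1 did the opposite, rising by 1.13 with siRNA and falling by 1.53 with H2O2, as did RNF43, rising by 2.76 and falling by 0.83. BMF rose in both, by 3.70 and 0.72. With slide as a block the H2O2 calls of HMOX1, ISL1 and RNF43 were lost. The comparisons share arrays, and whether such pairs are more frequent than chance was not tested.

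The ratio columns of the authors' deposited table are on a smaller scale than the scanner values. For BMF the authors' deposited table gives a ratio of 3.01 of siRNA over control, where the scanner values differ 13.0-fold. Over 24297 probes the slope of the log2 ratios was 0.437 for this comparison, near the log10 of e, 0.434.

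The siRNA effect reached 9438 genes, 57.1% of those tested. The other splits of the 6 arrays gave at most 2 genes. Of the 10 splits 1, the real one, gave 9438, but 10 splits are too few for a share under 0.05. Every other split mixes control and siRNA arrays, which adds the siRNA difference to the spread, so its low count decides nothing. A response to double-stranded RNA may contribute, since the controls had water. Of the tested interferon genes 53.3% rose, with a median of 0.33, while of all 16533 genes 4661 rose. Camera called this list higher with the preset correlation (adjusted p = 0.0237) but not with an estimated one (adjusted p = 0.359). The share and the median lay between bounds for and against such a response. Those bounds were set after the results were seen, so this outcome decides nothing. Position on the slide cannot be told apart from siRNA, which lay at even positions throughout. Between positions 1 and 2 and positions 3 and 4 only 2 genes differed. An effect of NR4A3 loss itself stays open, as NR4A3 was not measurable.

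Against slide and position as causes of the rise of immediate early genes and the fall of histone genes with H2O2, the smaller of both immediate early medians was 0.278 within slide 2 and 0.293 at equal position, above all 10000 random lists of equal size. For histones these medians were -0.366 and -0.393, below all random lists. The random lists were matched on mean signal but hold unrelated genes. They can understate how far members that move together shift on 1 array. Within that limit the medians of both lists argue against slide alone and position alone. With both as blocks the medians were 0.38 and -0.42 and camera called both lists at the preset correlation (adjusted p = 4.32e-10 and 3.25e-09), while with an estimated correlation, run without blocks, the immediate early call was lost (adjusted p = 0.0740) and the histone call held (0.0294). ATF3 then differed by 1.31 ± 0.14 (SE), against 1.40 ± 0.07, and 3 genes passed, as the SE grew and the residual degrees of freedom went from 5 to 3. Positions 3 and 4 of slide 2 together held only H2O2 arrays, so an effect of that place alone cannot be told apart from H2O2, nor can the 2 h later collection and extra handling of those dishes.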
